A study of Mus musculus with 6 samples.

How the data were processed

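RNA was sequenced from 6 mouse kidney samples, 3 with IRI and 3 with IRI and MK-8617. Per the labels' protocols, total RNA was isolated with TRIzol and libraries were made with the NEBNext Ultra RNA kit. Samples were grouped by their titles. The treatment entries of MK-8617 replicates 2 and 3 name MK8618 and MK8619, where the titles name MK8617, and the titles were followed. The design text speaks of tumors, while the labels name kidney, and the labels were followed. Nothing in the labels says that replicates came from separate animals, so the p-values measure the spread between these samples, which may be technical. The deposited column names carry a 1d tag, and the labels give no time after injury.

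Per the submitters' processing notes, the tools were CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0. The notes also name the human build GRCh38 (hg38), but the gene identifiers in the deposited table are mouse identifiers. The deposited signal values are gene counts that the authors divided by 1 size factor per library, with the authors' mean per group beside them. Each value was a whole multiple of what 1 read is worth in its library, so whole reads were recovered for 100% of values within a tolerance of 0.001. The raw read count is deposited for IRI replicate 3 alone, and the recovered reads equalled that deposited count in 7340 of 7340 genes. The deposited FPKM values are the authors' read counts scaled to gene length and library total. With exon lengths from GENCODE release M21 (GRCm38), FPKM and recovered reads gave the same library total for at least 95.3% of genes, and that total was taken as the library's depth. The authors' log2 fold changes, p-values and adjusted p-values were deposited too, and every listed p-value is below 0.05 (largest 0.0499). The deposited adjusted p-values imply an adjustment over 18811 genes, of which 11560 lie outside the table and were not analysed here. The table lists another 89 genes with a deposited adjusted p of 1, which do not count among the 18811. No direction can be given for a gene outside the table, and a list member outside it was not tested. Another 13 columns have no name or values and were not used, and 11 symbols that a spreadsheet had turned into dates were restored from the gene identifiers. Of the 7340 identifiers 7338 matched the GRCm38 annotation. Coordinates are those of whole genes, since reads were counted per gene and no exon, intron or UTR can be separated.

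The design fixed before the data were examined had assumed raw counts and edgeR. Because the values are normalised, limma 3.58.1 (trend and robust, R 4.3.3) was used on log2(value + 1), so a fold change is on the log2(value + 1) scale. The added 1 understates the change of low genes, but a fold change is a difference of mean logs, and where libraries of a group are unequal it can also exceed the ratio of the group means. Genes were filtered with filterByExpr of edgeR 4.0.16 on recovered reads and library totals, which left 6961 genes and removed 379. The limma p-values were adjusted by the Benjamini-Hochberg method over 18811 genes, since unlisted genes had been tested and left out, with a threshold of 0.05. The table's selection on p favours large differences, so shares of changed genes describe the table, not the transcriptome. A total of 28 gene lists was fixed before the data were examined. Of these 25 had at least 3 tested members and were compared with the other listed genes by camera on log2(value + 1), with a preset correlation of 0.01 and adjustment over the 25 lists. Its background is therefore the listed genes alone. With an estimated correlation 0 lists passed, against 12 with the preset one, and 3 lists had an unadjusted p below 0.05. Counts adjusted over the list alone counted unlisted members as tested.

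The rule for named genes, also fixed beforehand, took 11 genes of the HIF, injury and proliferation setting, the 12 largest rises and 12 largest falls, and up to 4 members of each list with the smallest adjusted p. The 24 largest changes were taken among called genes with a mean of at least 1 CPM, no overlap between groups and no predicted symbol. Their coding status was not checked. Members of a list that moved against its name or its direction were named after their values were seen. A few genes that the rule takes are not reported here.

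Size factors were 1.0566, 1.0979 and 1.0432 for IRI replicates 1, 2 and 3 and 0.9761, 0.937 and 0.9404 for the MK-8617 replicates, so that 1 read was worth 0.9108 to 1.0673 normalised reads. A floor of 3 reads per library, in CPM of the library total, corresponded to 0.154 to 0.178 CPM and covers counting error only, and 5 genes had 0 reads in all libraries of a group. None of them is a member of a fixed list. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 17.12 to 47.47, so no library was counted as a duplicate. The first principal component held 81.3% of the variance and separated the groups, and the labels give no sequencing batch.

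On simulated counts for 6961 genes with 200 changed, the limma step called 71% of 2-fold and 96% of 4-fold changes, called 3 unchanged genes and gave 0 wrong signs. In 5 simulations of 18811 unchanged genes, 869 to 917 passed a selection at p below 0.05 with edgeR, and at most 0 were then called. All simulations took means and dispersions from the listed genes, which had been selected on p. The first also changed far fewer genes than were called in the data. These rates therefore describe the simulations and need not hold for the table. Alternatives were edgeR, DESeq2 1.42.0 and limma-voom on recovered reads (edgeR called 5081 genes), other scalings, filters, pseudocounts of 0.5 and 10 and thresholds, the replicate number as a block, each library left out in turn, and fry. Scaling by library totals, removal of trends on transcript length and GC content (mgcv 1.9.3) and adjustment over the listed genes alone were chosen after seeing the data. The trends were fitted on genes selected at p below 0.05, which overstates them. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.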

Results

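Gene expression was measured by RNA sequencing in 6 mouse kidney samples from wild-type animals. In 3 samples the kidney had undergone ischaemia-reperfusion injury (IRI), in which the blood supply is interrupted and then restored. The other 3 samples came from IRI with MK-8617, an inhibitor of the prolyl hydroxylases that mark hypoxia-inducible factor (HIF) for degradation. The series title places the comparison in the setting of Sox9-positive renal progenitor cells and regeneration. The question addressed here is which transcripts differ between injured kidneys with and without the inhibitor. No uninjured sample was analysed here, so every difference is relative to IRI alone. Counted reads per library came to 18697479, 19508497 and 18620621 for IRI replicates 1, 2 and 3, and to 17577794, 16921662 and 16835541 for MK-8617 replicates 1, 2 and 3. The deposited table lists 7340 genes, each with a p below 0.05 in the authors' own comparison. These genes held 51.7% to 53% of the reads in the IRI libraries and 56.7% to 57.4% in the MK-8617 libraries. Counts of list members given below cover these listed genes only. The shares that rose or fell therefore describe members already selected at a p below 0.05.

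MK-8617 was accompanied by higher HIF target, glycolytic and fatty acid oxidation transcripts and by lower cell cycle, macrophage and matrix transcripts. None of these list calls held with an estimated correlation between genes (adjusted p of 0.07 to 0.56), and the macrophage call was also lost in 2 other settings given with its list. Egln3, a HIF-induced prolyl hydroxylase, had 898 ± 233 normalised reads with MK-8617 and 187 ± 31.7 with IRI alone (SD, n = 3 per group). Sox9, a transcription factor of tubular progenitor and repairing cells, had 1296 ± 207 against 449 ± 141. Havcr1, which encodes the tubular injury marker KIM-1, fell from 40353 ± 1946 to 14408 ± 968. Uhrf1, a DNA replication-associated factor, fell from 1507 ± 690 to 105 ± 4.65. Of 6961 genes tested, 5173 changed at an adjusted p below 0.05 in the limma test, 2482 of them higher and 2691 lower with MK-8617. Without MK-8617 replicate 1 the test called 3412 genes, 1488 of them higher, and without MK-8617 replicate 3 it called 1618 genes higher. By the authors' deposited table, 5656 genes had an adjusted p below 0.05, and 5052 of the genes called here were among them with the same direction. The groups did not overlap in 92.5% of the tested genes, against 10% by chance, but the table was itself selected on p.

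**Figure D1:**
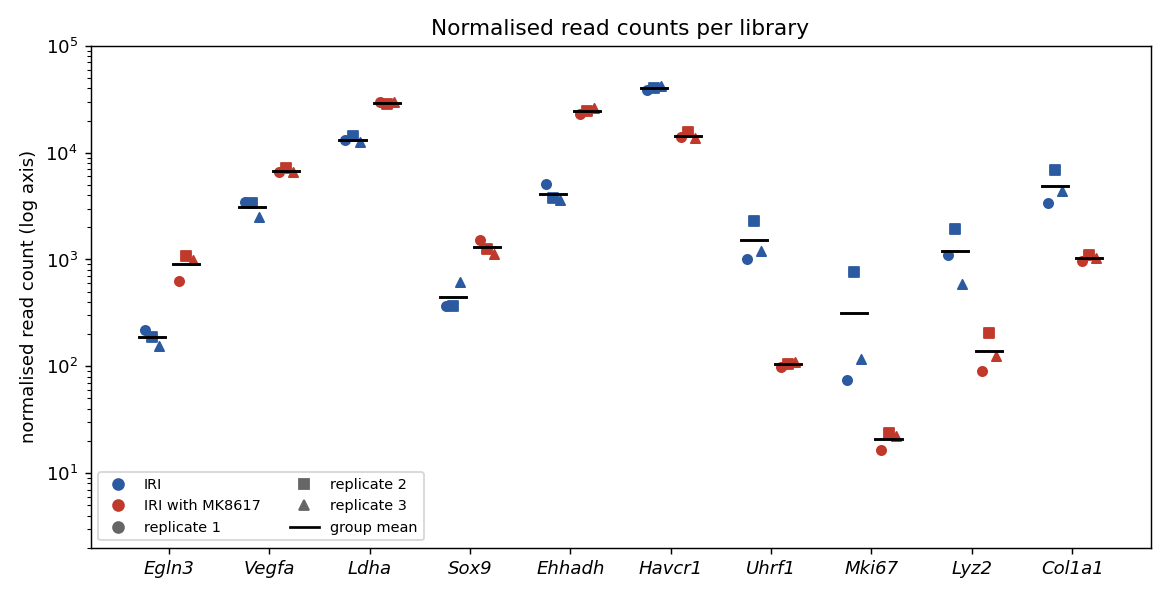
Normalised read counts of 10 genes in each of the 6 libraries, on a log axis, with IRI in blue, IRI with MK-8617 in red, a marker shape per replicate and a black line at the group mean. Egln3, Vegfa, Ldha, Sox9 and Ehhadh lie higher with MK-8617 in 3 of 3 libraries, while Havcr1, Uhrf1, Mki67, Lyz2 and Col1a1 lie lower in 3 of 3, and IRI replicate 2 holds the highest Mki67 value, 761.5.

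HIF target genes rose together. Of 27 tested members 24 rose and 1 fell, and adjusted over the list alone 25 rose and 2 fell. The median log2 fold change was 1.15, and camera placed the list above the other listed genes with an adjusted p of 1.3e-07, while the adjusted p was 0.07 with an estimated correlation. Bnip3, a mitophagy receptor (ENSMUSG00000078566, GRCm38 chromosome 7, 138890836 to 138909519), rose by a log2 fold change of 2.96 ± 0.14 (SE), from 794 ± 119 to 6192 ± 931 normalised reads. Its paralogue Bnip3l rose by 1.51 ± 0.09, Ndrg1 by 2.13 ± 0.15 and the transcriptional repressor Bhlhe40 by 1.51 ± 0.11. Vegfa, the endothelial growth factor gene, went from 3113 ± 539 to 6794 ± 399 normalised reads, a log2 fold change of 1.14 ± 0.14 with an adjusted p of 0.000702. It was 1.79 with the length and GC trends removed. That value rests on an annotated principal transcript of 654 nucleotides, in the shortest bin of coding genes (204 to 1080), and depends on this choice of transcript. Car9, a carbonic anhydrase, and Ankrd37 rose by 3.46 ± 0.27 and 3.98 ± 0.34. The member that fell was Car12, another carbonic anhydrase, at -1.13. Epo, the erythropoietin gene, was not among the listed genes and was not tested.

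Of the 7 tested genes of the HIF pathway itself 6 rose and 0 fell, with the same counts adjusted over the list alone. Egln1 and Egln3 are also in the HIF target list, so this list is not independent of it. The list median was 0.5 (camera adjusted p = 0.008, and adjusted p = 0.56 with an estimated correlation). Egln3 (GRCm38 chromosome 12, 54178981 to 54203860) rose by 2.24 ± 0.21 on the log2 scale and Egln1, the main HIF prolyl hydroxylase, by 0.87 ± 0.09. Hif1a and Epas1, which encode the alpha subunits HIF-1α and HIF-2α, rose by 0.74 ± 0.13 (adjusted p = 0.00402) and 0.5 ± 0.14 (adjusted p = 0.0249). With the length and GC trends removed Hif1a was at 0.48. Epas1 was no longer past the threshold without IRI replicate 1 (0.54), IRI replicate 2 (0.42), MK-8617 replicate 1 (0.47) or MK-8617 replicate 3 (0.41). It was also lost with the transcript length trend removed (0.35) and with the length and GC trends removed (0.4). Arnt2 rose by 0.47 ± 0.1, a call lost with the length trend removed (0.32). Egln2 was not listed and was not tested.

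Glycolysis and glucose uptake genes also rose. Of 15 tested members 12 rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 0.94. The camera adjusted p was 0.00037, and the adjusted p was 0.2 with an estimated correlation. Pfkl, the liver-type phosphofructokinase, rose by 1.93 ± 0.1 and Slc16a3, a lactate exporter, by 2.69 ± 0.19. Ldha rose by 1.14 ± 0.1, from 13292 ± 934 to 29303 ± 618 normalised reads, and Eno1 by 1.06 ± 0.1. Pfkm, the muscle-type phosphofructokinase, was the member that fell (-0.78). Gapdh, singled out after its values were seen, was not past the threshold (2.1 ± 0.73, adjusted p = 0.0745), with 8567 normalised reads in MK-8617 replicate 2 against 1185.4 and 1215.4 in the other two. It was past the threshold without MK-8617 replicate 2 (1.16) and with edgeR (2.76) or DESeq2 (2.77) on the recovered reads. Gapdh has many processed pseudogenes, so its counts are uncertain.

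Of 25 renal progenitor and nephron development genes 14 were tested. Among these 13 rose and 1, Ncam1, fell (-1.06), a call lost without MK-8617 replicate 1 (-1.01) or MK-8617 replicate 2 (-0.91). The counts adjusted over the list alone were the same, the median was 0.75 and the camera adjusted p was 0.0021, with an adjusted p of 0.51 with an estimated correlation. Sox9 (ENSMUSG00000000567, GRCm38 chromosome 11, 112782224 to 112787760) rose by 1.56 ± 0.21 with an adjusted p of 0.001 and was higher in 3 of 3 MK-8617 libraries. Myc rose by 1.36 ± 0.12, Lgr4, a receptor that potentiates WNT signalling, by 1.17 ± 0.11 and Lhx1, a transcription factor of the early nephron, by 1.36 ± 0.21. The number of members that rose was 8 without IRI replicate 2 and 7 without MK-8617 replicate 3, and it was 8 with the length trend removed. WNT pathway genes went both ways, with 2 higher and 3 lower among the 6 tested of 29 members (the same adjusted over the list alone) and a camera adjusted p of 1. Lrp5 and Lrp6, WNT co-receptors, rose by 0.76 ± 0.13 and 0.39 ± 0.11, and the WNT inhibitors Nkd1 and Sfrp1 fell, with log2 fold changes of -1.07 ± 0.17 and -0.67 ± 0.18. Lrp6 was not past the threshold without IRI replicate 1 (0.41), IRI replicate 2 (0.4), MK-8617 replicate 1 (0.33) or MK-8617 replicate 3 (0.35), nor with the length trend (0.23) or the length and GC trends (0.24) removed. Sfrp1 was not past it without IRI replicate 1 (-0.71). The third member that fell was Wnt4, a WNT ligand named after its values were seen (-1.18 ± 0.35, adjusted p = 0.0347). Its call was lost without IRI replicate 1 (-1.28), IRI replicate 2 (-0.96) or any 1 MK-8617 replicate (-1.2 to -1.17), and with DESeq2 on the recovered reads (-1.28).

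Tubular injury genes went both ways and were not called against the other listed genes (camera adjusted p = 0.45). Of 24 tested members 7 rose and 11 fell (9 and 13 adjusted over the list alone). Their median was -0.54, and fry, which tests a list against no change, gave an adjusted p of 0.011 for a fall. Every listed gene had been selected at p below 0.05, so that test was largely decided in advance, and it called 22 of 25 lists. With the length trend removed the median of the tubular injury list was -0.33. With the length and GC trends removed it was -0.26, with 8 members higher and 8 lower. Havcr1 (ENSMUSG00000040405, GRCm38 chromosome 11, 46735080 to 46779578) had a log2 fold change of -1.49 ± 0.11 with an adjusted p of 6.49e-05. S100a6, a calcium-binding protein gene, fell from 12128 ± 2522 to 1276 ± 163 normalised reads, a log2 fold change of -3.23 ± 0.17. The annexin genes Anxa2 and Anxa3 had changes of -1.64 ± 0.15 and -1.25 ± 0.1. Among those that rose were the fibrinogen chain genes Fga (2.37) and Fgg (2.17) and the lipid droplet gene Plin2 (2.26). Lcn2, which encodes the injury marker NGAL, was not listed and was not tested.

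Fatty acid oxidation genes rose, with 19 of 23 tested members higher and 1, Etfb, lower (22 and 1 adjusted over the list alone). The call of Etfb (-0.92) was lost with the length trend (-0.44) or the length and GC trends (-0.35) removed. The median of the list was 0.82 and the camera adjusted p 1.1e-06, with an adjusted p of 0.2 with an estimated correlation. The peroxisomal enzyme gene Ehhadh rose from 4138 ± 810 to 24390 ± 1581 normalised reads, a log2 fold change of 2.57 ± 0.14 with an adjusted p of 2.39e-05, and the fatty acid omega-hydroxylase genes Cyp4a14 and Cyp4a10 rose by 2.7 ± 0.19 and 1.69 ± 0.15. Cyp4a genes are close paralogues, and reads shared between them make the single values uncertain.

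Of 44 proximal tubule genes 20 were tested, with 10 higher and 1 lower (13 and 1 adjusted over the list alone). Their median was 1.09 and the camera adjusted p 0.0016, with an adjusted p of 0.56 with an estimated correlation. The organic anion transporter gene Slc22a8 rose by 1.85 ± 0.15, Cyp2e1 by 2.35 ± 0.25 and the bicarbonate transporter gene Slc4a4 by 1.6 ± 0.2, while Gatm, an enzyme of creatine synthesis, fell (-1.23 ± 0.22). Without MK-8617 replicate 1, and likewise without MK-8617 replicate 3, 6 members rose. With edgeR on the recovered reads 9 rose, and with the length and GC trends removed 12. Relative to the IRI mean, the median of the list was 0.36, 0.4 and -0.67 in IRI replicates 1, 2 and 3, so that IRI replicate 3 lay below the other two. Fatty acid oxidation enzymes are abundant in proximal tubule cells.

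Of 38 nuclear-encoded oxidative phosphorylation genes 18 were tested, with 13 lower and 1 higher (14 and 1 adjusted over the list alone). Their median was -0.51 and the camera adjusted p 0.0021, with an adjusted p of 0.56 with an estimated correlation. Cox5b, a cytochrome c oxidase subunit gene, had a change of -1.45 ± 0.16, the complex I genes Ndufa1 and Ndufb8 of -1.22 ± 0.17 and -0.88 ± 0.11, and the cytochrome c gene Cycs of -0.83 ± 0.1. Cox5b was at -0.95 with the length trend removed. Short transcripts as a whole were lower with MK-8617 across the table. With a trend on transcript length and GC content removed, 4 members were lower, the median was -0.19 and the camera adjusted p 0.23, and Ndufa1 (-0.41) and Ndufb8 (-0.21) were no longer past the threshold. Mitochondrially encoded genes went the other way, with 7 of 11 tested members higher and 0 lower (7 and 1 adjusted over the list alone), but the list was not past the threshold (camera adjusted p = 0.21). With DESeq2 on the recovered reads it was (adjusted p = 0.0087), and so it was with the length trend removed (adjusted p = 0.019), but not with the length and GC trends removed (adjusted p = 0.13). Cytochrome oxidase subunit mt-Co3 rose by 1.68 ± 0.21, mt-Nd5 by 1.05 ± 0.13, mt-Cytb by 0.75 ± 0.1 and mt-Nd6 by 0.8 ± 0.12 (1.54 with the length trend removed). The kit named in the labels is not described there as strand-specific, so reads of mt-Nd6 are uncertain where transcripts lie on the opposite strand.

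**Figure D2:**
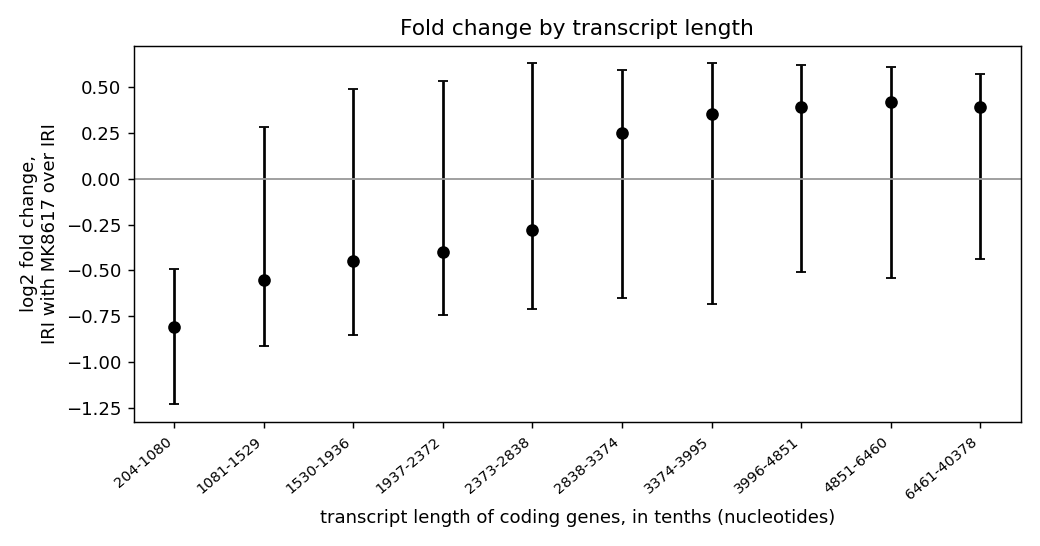
Log2 fold change of IRI with MK-8617 over IRI for protein-coding genes of the table in 10 equal-sized bins of transcript length in nucleotides, with the median as a point and the quartiles as bars. In the shortest bin, 204 to 1080 nucleotides, the median was -0.81 and 12% of genes were higher with MK-8617, and in the longest bin, 6461 to 40378 nucleotides, the median was 0.39 and 68.5% were higher.

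Cell cycle genes fell. Of 45 tested members 37 fell and 0 rose (41 and 0 adjusted over the list alone), with a median of -2.16. The camera adjusted p was 1.3e-07, and the adjusted p was 0.56 with an estimated correlation. Uhrf1 (GRCm38 chromosome 17, 56303321 to 56323486) had a change of -3.74 ± 0.26 with an adjusted p of 6.49e-05. The replicative helicase genes Mcm3 and Mcm2 had changes of -2.78 ± 0.23 and -2.32 ± 0.2, and the chromatin remodeller gene Hells of -3.47 ± 0.31. Mki67, the proliferation marker, had 74.8, 761.5 and 116.9 normalised reads in IRI replicates 1, 2 and 3 against 20.7 ± 3.8 with MK-8617. The change was -3.14 ± 0.72 (adjusted p = 0.0119), or -2.14 without IRI replicate 2 and -3.8 without IRI replicate 1. Mki67 was not past the threshold without MK-8617 replicate 1 (-2.99) or MK-8617 replicate 3 (-3.2), or with limma-voom on the recovered reads (-3.19). Relative to the IRI mean, the list median was -0.66, 1.09 and -0.39 in IRI replicates 1, 2 and 3 and -2.15, -2.2 and -2.17 in the MK-8617 replicates. Without IRI replicate 2, 35 members fell and the median was -1.66. Macrophage markers moved in the same direction.

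**Figure D3:**
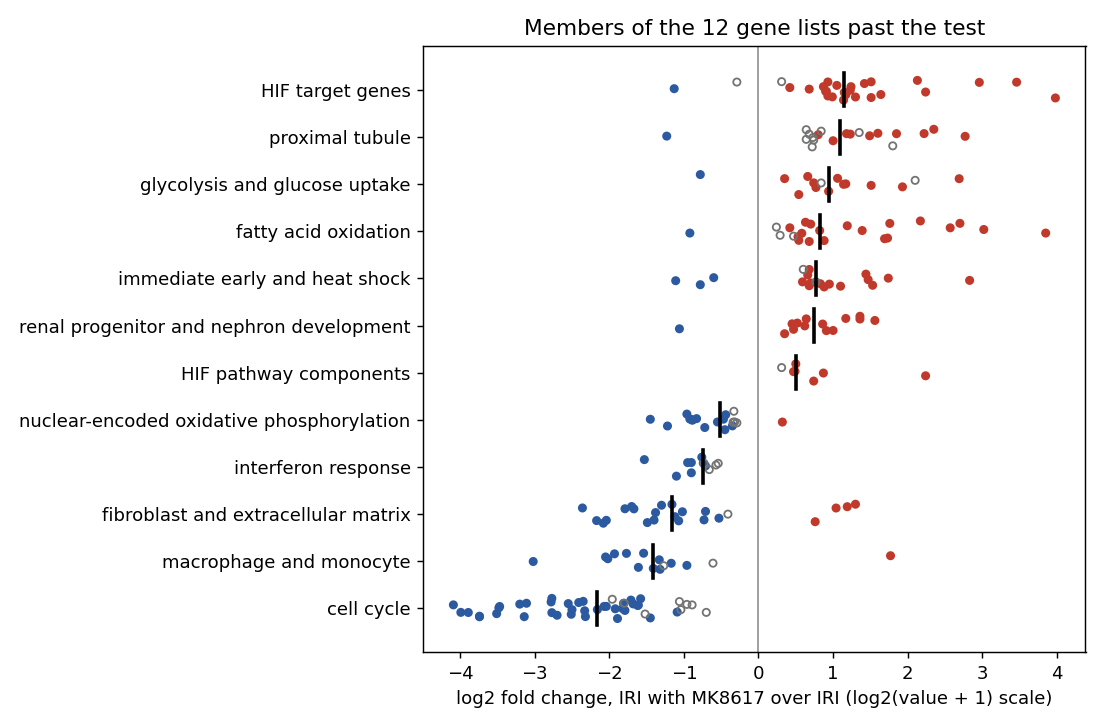
Log2 fold changes of IRI with MK-8617 over IRI, on the log2(value + 1) scale, for the tested members of the 12 gene lists past the camera threshold. Each point is a gene, filled red (higher) or blue (lower) where its adjusted p was below 0.05 and open otherwise, with a black bar at the list median, which ran from -2.16 for cell cycle genes to 1.15 for HIF target genes.

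Macrophage and monocyte genes were lower in 12 of 15 tested members and higher in 1 (13 and 1 adjusted over the list alone). The median was -1.41 and the camera adjusted p 0.012, with an adjusted p of 0.56 with an estimated correlation. Lyz2, the macrophage lysozyme gene, had a change of -3.02 ± 0.41, and the complement genes C1qc and C1qa of -1.54 ± 0.19 and -1.32 ± 0.2, with C1qa at -0.84 once the length and GC trends were removed. The member that rose was Cd14, a lipopolysaccharide co-receptor gene also expressed by tubular cells, at 1.77 ± 0.1. Without IRI replicate 2, 7 members fell. The list was not past the threshold with DESeq2 on the recovered reads (adjusted p = 0.056) or among genes with a mean of at least 5 CPM (adjusted p = 0.059), where 7 of 10 tested members fell. Interferon response genes were lower in 8 of 12 tested members and higher in 0 (9 and 0 adjusted over the list alone), with a median of -0.75. The camera adjusted p was 0.0084, and the adjusted p was 0.56 with an estimated correlation. Bst2 had a change of -1.53 ± 0.12 (-0.92 with the length and GC trends removed), the RNA sensor gene Ddx58 of -0.76 ± 0.13, Ifit3 of -0.9 ± 0.19 and Ifit2 of -0.71 ± 0.16. Without IRI replicate 2, 5 members fell, and Ifit2 was not past the threshold without IRI replicate 1 (-0.65).

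Inflammatory cytokine and adhesion genes were not called as a list (camera adjusted p = 0.14), although 10 of 16 tested members rose and 2 fell (10 and 3 adjusted over the list alone). The leukaemia inhibitory factor gene Lif rose by 2.69 ± 0.39, the neutrophil chemokine gene Cxcl1 by 1.69 ± 0.2 and Socs3, a feedback inhibitor of cytokine signalling, by 1.41 ± 0.16, while the interleukin-1 receptor antagonist gene Il1rn fell (-1.69 ± 0.32). Without IRI replicate 1 the number that rose was 6, and without MK-8617 replicate 3 it was 5. The number that fell was 4 without IRI replicate 3, and 5 of 19 members fell with no filter on low values. Neutrophil genes were not called (6 tested, 1 higher and 2 lower, or 1 and 1 adjusted over the list alone, camera adjusted p = 0.65). Ngp, a granule protein gene, rose from 1.91 ± 2.54 to 27.4 ± 12.3 normalised reads (an IRI mean of 0.473 without IRI replicate 3), and S100a9 and S100a8 fell, with changes of -1.29 ± 0.3 and -1.33 ± 0.4. Both S100a9 and S100a8 lost their call without MK-8617 replicate 1 (-1.1 and -1.06), without MK-8617 replicate 3 (-1.12 and -1.08) and with the length trend (-0.56 for both) or the length and GC trends (-0.59 and -0.6) removed. S100a8 also lost it without IRI replicate 1 (-1.39), without IRI replicate 2 (-1.11) and with edgeR on the recovered reads (-1.17). Of 21 lymphocyte genes 2 were listed and 0 had enough reads to be tested.

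Fibroblast and extracellular matrix genes were lower in 18 of 23 tested members and higher in 4 (19 and 4 adjusted over the list alone). The median was -1.16 and the camera adjusted p 0.0033, with an adjusted p of 0.56 with an estimated correlation. The collagen gene Col1a1 fell from 4869 ± 1798 to 1036 ± 67.7 normalised reads, a log2 fold change of -2.17 ± 0.22. Col5a1 had a change of -1.67 ± 0.17, Col15a1 of -1.3 ± 0.12 and Loxl2, a collagen cross-linking enzyme gene, of -1.38 ± 0.13. Among the 4 that rose were Cyr61 (1.3) and Thbs1 (1.19), which are genes induced by growth factors in many cell types, and the proteoglycan gene Dcn (0.76), the last not past the threshold without MK-8617 replicate 1 (0.72) or MK-8617 replicate 3 (0.78).

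Immediate early and heat shock genes were higher in 14 of 19 tested members and lower in 3 (16 and 3 adjusted over the list alone), with a median of 0.77. The camera adjusted p was 0.0061, and the adjusted p was 0.56 with an estimated correlation. The immediate early genes Egr1, Btg2 and Junb rose by 1.47 ± 0.19, 1.44 ± 0.21 and 0.88 ± 0.11. All 3 members that fell encode heat shock proteins, namely Hspa1b (-1.11 ± 0.13), Hspb1 (-0.78) and Hspa1a (-0.6), of which Hspa1a and Hspa1b are near-identical copies and therefore uncertain. Only Hspa1b stayed past the threshold without IRI replicate 1, without MK-8617 replicate 1, without MK-8617 replicate 2 and with the length and GC trends removed, where Hspb1 was at -0.84, -0.73, -0.8 and -0.26 and Hspa1a at -0.49, -0.67, -0.42 and -0.52. Hspb1 was also lost without MK-8617 replicate 3 (-0.83) and with the length trend removed (-0.31), and was at -0.5 without IRI replicate 3. Hspa1a was also lost with library sizes without the most abundant genes (-0.53). Without MK-8617 replicate 1, and likewise without MK-8617 replicate 3, 8 members rose.

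The other nephron segments and cell types gave no list past the threshold. In the thick ascending limb list 1 of 7 tested members rose and 5 fell (the same adjusted over the list alone, camera adjusted p = 0.25). Slc12a1, the salt cotransporter of that segment, Cldn10 and Ppp1r1a had changes of -1.7 ± 0.21, -1.94 ± 0.3 and -1.2 ± 0.18, while Egf rose by 2.24 ± 0.28. Distal and connecting tubule genes were higher in 3 of 6 and lower in 0 (4 and 1 adjusted over the list alone, camera adjusted p = 0.3). The magnesium channel gene Trpm6 rose by 1.55 ± 0.23, Pvalb by 2.65 ± 0.5 and the calcium channel gene Trpv5 by 0.93 ± 0.22, the last not past the threshold without MK-8617 replicate 1 (0.75) or MK-8617 replicate 3 (0.86). In the collecting duct list 1 of 8 rose and 4 fell (the same adjusted over the list alone, camera adjusted p = 0.26). The proton pump genes Atp6v1b1 and Atp6v1g3 had changes of -2.15 ± 0.17 and -1.26 ± 0.2 and Fxyd4 of -1.12 ± 0.2, while the anion exchanger gene Slc4a9 rose by 1.67 ± 0.16. Podocyte genes were higher in 3 of 5 and lower in 1 (the same adjusted over the list alone, camera adjusted p = 0.21), with Wt1 at 0.91 ± 0.2, Nphs1 at 0.42 ± 0.11 and Nes at -0.54 ± 0.16. Nphs1 was not past the threshold without MK-8617 replicate 1 (0.38) or with the length trend removed (0.28). Nes was not past it without IRI replicate 1 (-0.56), IRI replicate 3 (-0.39), MK-8617 replicate 1 (-0.54) or MK-8617 replicate 2 (-0.43), or with TMM scaling (-0.48) or library sizes without the most abundant genes (-0.46). Of 22 endothelial genes 5 were tested, with 2 higher and 0 lower (the same adjusted over the list alone, camera adjusted p = 0.48). The VEGF receptor gene Flt1 rose by 0.98 ± 0.17 and Sox18 by 0.79 ± 0.13. The lowest log2 fold change among the tested endothelial members was -1.43, not past the threshold. With edgeR on the recovered reads 2 endothelial members rose and 1 fell.

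Among erythrocyte and platelet genes 2 of 3 tested members fell and 0 rose (the same adjusted over the list alone, camera adjusted p = 0.2), with log2 fold changes of -1.93 ± 0.39 for Pf4 and -0.58 ± 0.1 for Bpgm. Pf4 was at -1.27 with the length and GC trends removed. NRF2 target and oxidative stress genes were higher in 3 of 15 and lower in 8 (the same adjusted over the list alone, camera adjusted p = 0.44). The glutathione transferase genes Gsta2 and Gsta1, which are close paralogues and uncertain, had changes of -1.15 ± 0.13 and -1.67 ± 0.3, the peroxiredoxin gene Prdx1 of -0.8 ± 0.12, and the haem oxygenase gene Hmox1 rose by 0.94 ± 0.13. Gsta2 was at -0.65 with the length trend removed. Genes of the p53 response and cell death went both ways, with 5 higher and 5 lower of 12 (5 and 7 adjusted over the list alone, camera adjusted p = 0.65). Phlda3, Bak1 and Ccng1 had changes of -1.64 ± 0.16, -0.92 ± 0.11 and -0.62 ± 0.1, and Acsl4 rose by 0.79 ± 0.15, a call lost with the length and GC trends removed (0.4). The number of this list that rose was 3 without IRI replicate 1, without MK-8617 replicate 1 and without MK-8617 replicate 2. With the length and GC trends removed 2 were higher and 5 lower. Both tested members of the adrenal, adipose and muscle list rose (2 and 0 adjusted over the list alone), too few for a list test. They were the lipid droplet genes Cidec (1.89 ± 0.24) and Plin1, the latter at 38.2 ± 2.58 against 0.623 ± 0.54 normalised reads. The Y-linked gene Ddx3y was detected in all 6 libraries and rose by 0.45 ± 0.14 (adjusted p = 0.044), but not adjusted over the list alone. That call was lost without IRI replicate 1 (0.4), IRI replicate 2 (0.38), MK-8617 replicate 1 (0.37) or MK-8617 replicate 3 (0.4). It was also lost with upper quartile scaling (0.4), library totals as scaling (0.43), a mean of at least 5 CPM (0.45) and the length trend removed (0.31), and with the length and GC trends removed the sign changed (-0.06).

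The 12 genes with the largest rises under the rule for named genes included Car9, Ankrd37 and Plin1, whose values are given with their lists. Mt2, a metallothionein gene, went from 52.8 ± 34.9 to 2515 ± 288 normalised reads, a log2 fold change of 5.76 ± 0.4 with an adjusted p of 6.16e-05 and an IRI mean of 33.6 without IRI replicate 3. Adm2, a peptide hormone gene of the adrenomedullin family, rose by 3.62 ± 0.2. The sulfotransferase gene Sult1e1 went from 36.2 ± 30.9 to 253 ± 53.9 normalised reads, a log2 fold change of 3.43 ± 0.82 in limma and 2.81 with edgeR on the recovered reads. IRI replicate 2 held 3.6 normalised reads of Sult1e1, and without it the change was 2.27. Without IRI replicate 3 the change was 4.18 and the IRI mean 21.7, and the call was lost without MK-8617 replicate 3 (3.26). Cyp2j8 rose by 4.95 ± 0.76, the chemokine scavenger gene Ackr2 by 4.32 ± 0.78, AW822252 by 3.46 ± 0.45, Trim67 by 3.41 ± 0.54 and Marc1 by 3.12 ± 0.42. Without IRI replicate 2 Cyp2j8 was at 3.91, and Ackr2 was at 5.29 without IRI replicate 1 and 3.6 without IRI replicate 3. Among the 12 largest falls, Dtl, a replication-coupled ubiquitin ligase adaptor, went from 287 ± 127 to 6.71 ± 3.15 normalised reads, a log2 fold change of -5.24 ± 0.43. Fignl1 had a change of -4.17 ± 0.35, Exo1 of -4.68 ± 0.56, Clspn of -4.54 ± 0.57, Dscc1 of -4.72 ± 0.7, Melk of -4.4 ± 0.82 and Pclaf of -4.33 ± 0.72, the last lost with limma-voom (-4.44). IRI replicate 2 held the highest values of Melk and Pclaf, and without it their IRI means went from 75.2 ± 80 to 29.1 and from 268 ± 304 to 92.9, with log2 fold changes of -3.57 and -3.42. Clspn was then at -3.91, and Dscc1 was at -4.01 without MK-8617 replicate 3 and at -5.34 without MK-8617 replicate 2. Lrr1 had 0 reads in the 3 MK-8617 libraries and 43.7 ± 43 normalised reads with IRI, at least 13.8-fold lower against a floor of 3 reads per library. Without IRI replicate 2 the IRI mean was 19.1 and Lrr1 was at least 6.05-fold lower. Aunip, Pbk and Esco2 had 74.3 ± 65.6, 106 ± 128 and 64.6 ± 82.2 normalised reads with IRI and 0.354 ± 0.614, 1.06 ± 1.84 and 1.05 ± 1.06 with MK-8617. Their IRI means were 36.7, 32.4 and 17.2 without IRI replicate 2, and their MK-8617 means 0, 0 and 0.512 without MK-8617 replicate 3. A pseudocount of 10 brought low genes nearer to 0, with Ackr2 at 2.3, Cyp2j8 at 3.25, Trim67 at 1.95, Marc1 at 1.77 and Pvalb at 1.74. Exo1, Dscc1, Melk and Klk1b11 were then at -3.09, -2.71, -2.43 and -2.62. Klk1b11, a kallikrein gene with close paralogues and therefore uncertain, had a change of -4.47 ± 0.8, or -3.59 without MK-8617 replicate 1 and -5.42 without MK-8617 replicate 2.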

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

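Library totals, the length and GC corrections and adjustment over the listed genes alone were chosen after the data were seen, and the other alternatives before. Leaving out each library in turn, so that fewer samples enter each fit, gave 3412 to 5144 changed genes and 1488 to 2446 higher genes. The lowest of both came without MK-8617 replicate 1. With an absolute log2 fold change of at least 1 required, 1846 genes changed, 734 higher and 1112 lower. Count tests on the recovered reads called 5081 (edgeR), 5460 (DESeq2) and 4989 (limma-voom) genes. Higher genes made up 48% of calls, and 41.8% to 56.7% under the other scalings, which moved the median of all genes by at most 0.08.

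Camera with an estimated correlation called 0 of the 25 lists, the HIF target list included (median 1.15, adjusted p = 0.07), with 3 lists at an unadjusted p below 0.05. By contrast fry, which does not compare a list with other genes, called 22. All tested genes had been selected at p below 0.05, so a test against no change was largely decided in advance. The estimated-correlation version refers its statistic to the few residual degrees of freedom of 6 libraries, which weakens it by construction, and it uses correlations that were in part far above the preset 0.01. They were 0.8 for cell cycle, 0.72 for proximal tubule, 0.7 for oxidative phosphorylation, 0.58 for macrophage and 0.49 for immediate early genes, but -0.01 for HIF target genes. With the preset correlation, the HIF target list had adjusted p values of 5.3e-15 to 6.7e-07 over the other settings. Oxidative phosphorylation ranged from 0.00019 to 0.24, macrophage genes from 0.0018 to 0.059 and mitochondrially encoded genes from 0.0087 to 0.35, and the other 9 called lists kept their call in each setting with that correlation. Of 122 named genes, Ddx3y changed sign (-0.06 with the length and GC trends removed), and the cause was not tested. Leaving out 1 library at a time kept the call of a named gene 702 times and ended it 30 times. Removing the length trend ended 9 named gene calls and removing the length and GC trends 7, besides that of Ddx3y. Same-numbered libraries had correlated deviations of 0.02, 0.12 and 0.11, against -0.13 to 0.02 otherwise, so the numbers were not taken as pairs. IRI replicate 1 correlated equally, at 0.02, with MK-8617 replicates 1 and 2. A replicate block gave 5257 genes and changed no list call and no call of the 122 named genes, while Wnt4, named after its values were seen, had an adjusted p of 0.0532 and 4 inflammatory genes fell in place of 2. Genes under 3 reads per library cannot be read for direction at this depth.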

Other observations

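All tests of explanations below were chosen after the result was seen, except the splits of the libraries. Ribosomal protein genes, a class outside the fixed lists, were lower with MK-8617 in 75 of 77 tested genes and higher in 1, Rpl24, with a median log2 fold change of -0.92, while the scalings moved the median of all genes by at most 0.08. Rps29, a small ribosomal subunit gene, went from 10375 ± 1263 to 812 ± 182 normalised reads (SD, n = 3 per group), a log2 fold change of -3.69 ± 0.17 (SE). Rps28 went from 6433 ± 893 to 543 ± 93.6, a change of -3.57 ± 0.15. Both were named after their values were seen, and their falls were far larger than the class median. With the length and GC trends removed Rps29 was at -2.79 and Rps28 at -2.66. Rpl24 rose from 23.5 ± 7.52 to 125 ± 12.4, at a low level for this class, and reads shared with pseudogene copies make its value uncertain. Processed pseudogenes were lower in 170 of 271 and higher in 44, with a median of -1.13.

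Short mRNAs were lower with MK-8617. Across 6065 coding genes that encode neither ribosomal proteins nor oxidative phosphorylation subunits, the log2 fold change rose with transcript length (Spearman rho 0.25 across genes, which are not independent replicates, permutation p = 1e-04, the smallest the permutations can give). This is consistent with a length-dependent difference between the sets of libraries, such as in RNA integrity or fragment selection. For the shortest and longest bins of coding genes, each gene was centred on its mean over the 6 libraries. The difference of their medians was 0.48, 0.73 and 0.5 in the IRI libraries and -0.44, -0.47 and -0.78 in the MK-8617 libraries. Every gene had been selected for a difference between these groups, so this split by group was largely decided in advance and adds no separate support. A biological cause stays open and untested. Ribosomal protein genes lay a further -0.4 below coding genes of matched length and expression, below all of 10000 matched sets. The range of -0.5 to -0.34 covers the random choice of matched genes only, not the spread between libraries or among ribosomal protein genes. Genes of the class may move together, so the share of matched sets may overstate the support. With the trends removed the class median was -0.49 and 42 members still fell, as a fall of the class beyond the trend would give. Within the class the log2 fold change also rose with length (Spearman rho 0.42, permutation p = 3e-04 across genes). Processed pseudogenes differed from matched coding genes by 0.05 (-0.07 to 0.16, again over the choice of matched genes only), so they did not lie below them. The matched genes were chosen by length and expression, not as parent genes. The comparison therefore cannot decide whether reads moved between pseudogenes and other genes.

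The fall of cell cycle genes had a median of -2.16. With the length and GC trends removed it was -2.08, and without IRI replicate 2, where the list was highest, 35 members still fell, which argues against either as the whole cause. A lower share of macrophage RNA cannot be told apart from a fall within cells. Medians of 2 gene lists in kidney tissue RNA cannot separate cell shares from expression within cells, however stable they are. Besides, 1 library decided the comparison. The cell cycle median minus that of macrophage and monocyte genes was -0.75 (two-sided permutation p = 0.012 across genes, which are not independent), but without IRI replicate 2 it was -0.36 (p = 0.14). A loss of dividing cells of any type, or a later or earlier stage of repair, may contribute and was not tested, and no time after injury is given.

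The rise of fatty acid oxidation genes kept a median of 0.86 with the length and GC trends removed, which argues against those trends. A larger share of proximal tubule RNA cannot be told apart from induction of the pathway. The list's median differed from that of proximal tubule genes by -0.27 (two-sided permutation p = 0.63 across genes), and the enzymes are abundant in those cells. Feeding state, which may also change Cyp4a genes, was not tested.

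Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many changed genes in the limma test, namely the real one with 5173, and the highest of the others gave 0 (7 to 116 at an unadjusted p below 0.05). With 10 splits the share cannot go below 0.1, and the table was selected on the real split.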
